A study of Homo sapiens with 7 samples.

How the data were processed

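The data are 7 Affymetrix genome-wide expression arrays of Panc1, an established human pancreatic cancer cell line. Per the labels, the cells had been transfected with an expression vector that carries S100P with a V5-His tag, or with the same vector without S100P, and single-cell clones had been isolated. S100P is a small calcium-binding protein of the S100 family. There were 4 arrays of clones labelled S100P overexpressing, 2 each of clone 1 and clone 5. There were 3 arrays of vector clones, 2 of clone V3 and 1 of clone V1. Arrays of one clone are called a and b after the letter in their labels.

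The deposited values were made by the authors with RMA, which corrects background, normalizes between arrays and summarises probes into probe sets, per the submitters' processing notes. The deposited table does not state its scale in words. Its values ran from about 2 to 14 on every array, a range of log2 values, and they were used as log2 values as deposited. The RMA version, and whether the 7 arrays were processed together, are not given in the sources used here. Detection calls and scanner files were not used here, so no probe set could be called absent and the number of arrays limits the precision. RMA can compress differences of dim probe sets, and a fold against a dim group is open for that reason. The array medians lay between 4.51 and 4.58. Between 4.51% and 9.21% of the probe sets had an identical value on any 2 arrays, also between clones, so no pair of arrays looked like 1 array deposited more than once.

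The table held 54675 probe sets, of which 62 were controls and 54613 were tested. In the platform annotation 41091 of the tested probe sets had 1 gene symbol, 1801 had several and 11721 had none. Genes were named only from the first kind. Of these, 41037 matched a current gene by its Entrez number, and 0 symbols needed an update. A gene was represented by its probe set of highest mean over the 7 arrays, which gave 19775 genes. Other probe sets are mentioned for some genes only, so silence on them does not mean that they moved alike.

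Tests used limma 3.58.1 and statmod 1.5.0 in R 4.3.3, and figures used matplotlib 3.10.9. The comparison of arms fitted the group as the fixed effect with the clone as a random block (duplicateCorrelation), since arrays of a clone are not independent. The consensus correlation within a clone was 0.287. The fitted differences weight arrays by that correlation and so differ slightly from differences of plain means. The same correlation served every probe set. Some genes differ far more between clones of an arm than between arrays of a clone. RAB27B, for instance, read 10.62 and 10.46 on clone 1 but 9.33 and 9.28 on clone 5. For such genes the arrays count as more independent than they are, and the adjusted p may be too small. Differences between single clones were taken from a second limma fit with the 4 clones as fixed effects. In that fit the spread is that between arrays of one clone, with 3 residual degrees of freedom, so it compares these clones and not conditions. V1, with 1 array, is assumed there to vary like the other clones. Where a clone was compared with the vector arm, V1 and V3 had equal weight. Tests were two-sided with Benjamini-Hochberg adjustment over the 54613 probe sets, at an adjusted p of 0.05. The labels do not say whether arrays a and b came from separate cultures, so p-values measure only the spread between these arrays and clones, which may be technical in part.

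A set of 24 gene lists, with S100P kept out of each, was fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. The lists were tested with limma's cameraPR on the moderated statistics with a preset correlation of 0.01. Camera with an estimated correlation, without the clone block, and fry with the clone block were run beside it. The lists cover the S100 family, S100P partners, adhesion receptors, proteases of invasion, epithelial and mesenchymal markers, actin regulators, extracellular matrix, ERK response, NF-kB targets, type I interferon response, cell cycle, TGF-beta targets, Wnt targets, hypoxia and glycolysis, unfolded protein and amino acid stress, cholesterol synthesis, ductal markers, acinar cells, endocrine cells, fibroblasts, leukocytes, endothelial cells and genes used by nearly all cells.

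Named genes were S100P, the 15 higher and 15 lower genes of largest log2 difference that passed the threshold with all S100P-labelled arrays on one side of all vector arrays, and up to 4 members of each list that passed. Where no member of a list passed, up to 2 of largest difference were taken, as values. From the contrasts of clone 5 minus clone 1 and V1 minus V3, the 8 genes of largest difference in each direction were taken. Sex-linked marker genes and uncharacterised symbols were left out.

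RNA quality was read from the 3' and 5' control probe sets of ACTB and GAPDH with exact permutation tests over the arrays. The fits were tested on simulated data with 54613 probe sets, spread between clones and known changes of the arm comparison. That comparison recovered 77.9% of changes of 1 on the log2 scale, 97.0% of changes of 2 and 100% of changes of 3. Of its calls 0.543% were false, against 23.2% without the clone block. With clone spreads that differed between probe sets and no change, the arm comparison made 21 false calls. The rates of recovered and false calls used a clone SD of 0.127, and the simulated correlation within a clone was 0.537, against 0.287 in the data. In the data, log2 differences had an SD of 0.291 between clones 1 and 5 and 0.435 between V3 and V1, over 17980 probe sets. The simulated rates hold for the simulated setting only and do not give the share of false calls in the real data. Alternatives were fits without the block, on clone means, with the array letter as a block, without each array or clone, other normalizations, a filter on dim probe sets (mean log2 of at least 6 in 1 group), an intensity trend, array weights, other thresholds and other list tests.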

Results

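RNA of 7 Panc1 arrays was compared in order to find genes regulated by S100P. The S100P-labelled arm held 4 arrays of 2 clones, and the vector arm held 3 arrays of 2 clones. On each array 32.1% to 33.3% of the probe sets had a log2 value of at least 6. Arrays of the same clone correlated at r = 0.996 to 0.998 across probe sets. The V1 array correlated with the other arrays at 0.982 to 0.990.

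S100P itself was not detectably higher on the arrays labelled S100P overexpressing. Its 1 probe set read 5.80 and 5.95 on the arrays of clone 1, and 5.36 and 5.45 on those of clone 5. It read 5.65 and 6.01 on the V3 arrays and 4.65 on the V1 array. The fitted log2 difference was 0.27 (SE 0.32, limma adjusted p = 0.846). An exact two-sided permutation test gave p = 0.714 over the 7 arrays and p = 0.667 over the clone means, where the smallest possible p is 0.333. The fitted difference was -0.19 without V1 and 0.49 without V3 array b. It was 0.99 without clone V3 (adjusted p = 0.117), -0.16 without clone 1 and 0.41 without clone 5, so its sign turned on which clones were included. Whether this probe set reads the transgene is unknown here, so it does not settle the labels, and every direction below is that of the arms as labelled.

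**Figure D1:**
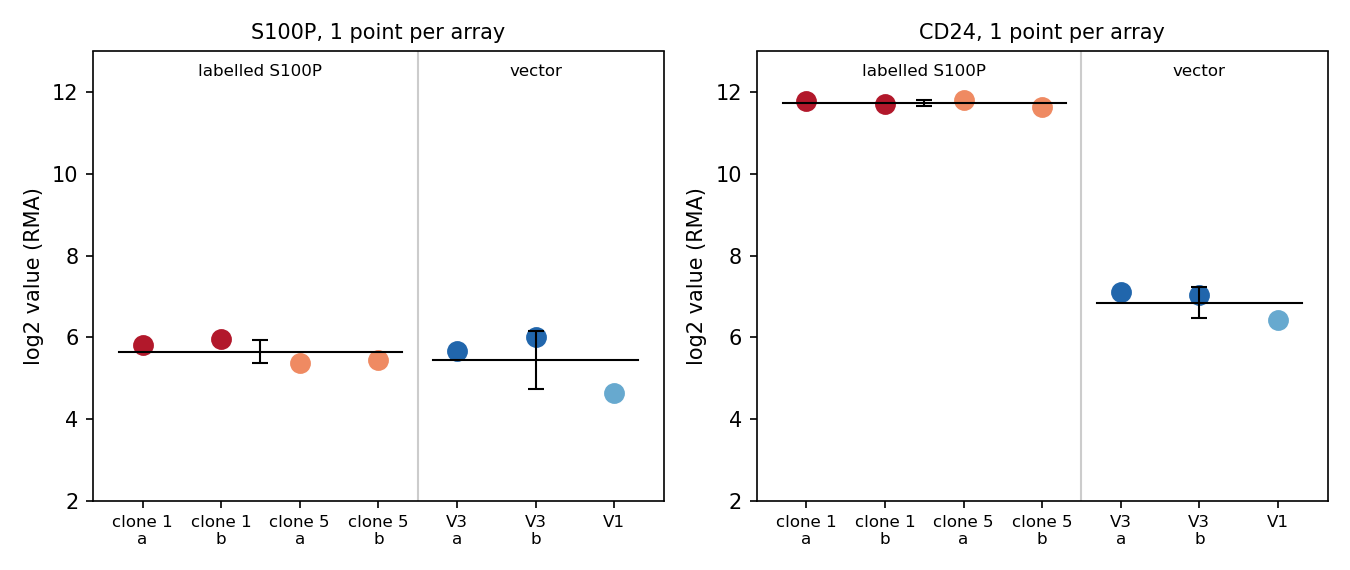
Log2 values (RMA) of S100P on the left and CD24 on the right, 1 point per array, with lines at the mean of each arm and bars of 1 SD. S100P lies between 4.65 and 6.01 in both arms, while CD24 lies between 11.64 and 11.82 on the S100P-labelled arrays and between 6.42 and 7.10 on the vector arrays.

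The surface glycoprotein CD24 rose most in the S100P-labelled clones, 30.5-fold (log2 difference 4.93, SE 0.17, limma adjusted p = 1.16e-05, 4 against 3 arrays). All 6 CD24 probe sets rose, from 11.2-fold to 31.1-fold. They are of types that can also read near-identical transcripts, so CD24 is uncertain to that extent. KLHL13, an adaptor of a cullin ubiquitin ligase, rose 19.6-fold (SE 0.20, adjusted p = 6.94e-05). RAB27B, a GTPase of vesicle secretion, rose 15.2-fold (SE 0.34, adjusted p = 0.00211). Its other probe sets, 1.9-fold and 2.3-fold higher, were not called. FAM107B rose 9.81-fold, the Wnt pathway modulator DACT2 8.76-fold, and the fibrillar collagen gene COL11A1 8.47-fold. Without V1 they rose 7.58-fold, 11.6-fold and 5.1-fold. The transcription factor FOXP1 rose 7.57-fold at the probe set of highest mean and 8.66-fold and 5.07-fold at 2 other ones, while its remaining 5 were not called. CD55, which protects cells from complement, rose 6.74-fold at that probe set and 6.82-fold and 7.47-fold at the other ones. The desmosomal cadherin DSC2 rose 5.13-fold. SNHG24, SLC16A14, IGFBPL1, the histone gene H2BC21, TMEM45A and the scaffold gene SASH1 rose between 4.42-fold and 7.86-fold. The vector means of KLHL13 (4.39), DACT2 (4.35) and SLC16A14 (4.2) lay below the median of every array, so the size of those folds is open.

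TMEM47, a membrane protein of cell junctions, was 36.4-fold lower in the S100P-labelled clones (SE 0.30, adjusted p = 2.76e-04). At its other probe set it was 6.30-fold lower, also called. IFITM1, an interferon-induced membrane protein, was 24.9-fold lower (SE 0.47, adjusted p = 0.00470). Without V1 it was 42.0-fold lower. EDIL3, a secreted ligand of integrins, was 13.9-fold lower, and CRACD, a regulator of actin capping, 13.6-fold lower. The other EDIL3 probe sets were 1.2-fold and 1.6-fold lower and not called. CRACD was 2.77-fold lower at another probe set, also called, and level at the remaining probe set. The Rac activators DOCK4 and TIAM1 were 8.62-fold and 7.43-fold lower. The other DOCK4 probe sets were 1.04-fold to 1.16-fold lower and not called. The other TIAM1 probe set was 1.58-fold lower and called. The secreted pentraxin PTX3 was 8.46-fold lower (SE 0.12, adjusted p = 1.90e-05). KMO, an enzyme of tryptophan breakdown, was 6.85-fold lower. The morphogen gene SHH was 6.52-fold lower and the guidance cue gene NTN1 5.20-fold lower. Neither was called at any other probe set. ALPG, an alkaline phosphatase with a near-identical relative, was 10.6-fold lower and is uncertain for that reason. Without V1 it was 21.2-fold lower, so its size also turned on that array. OPN3, PPP1R9A, CDS1 and IFIT3 were 4.58-fold to 5.12-fold lower. PPP1R9A was not called at any other probe set. CDS1 was called at another probe set, 2.69-fold lower, and not called at its remaining ones. In 8 of these 15 genes the S100P-labelled mean lay below the median of every array, as in TMEM47 with 3.14 ± 0.06 (SD, n = 4) against 8.40 ± 0.72 (SD, n = 3), so the size of such folds is open.

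**Figure D2:**
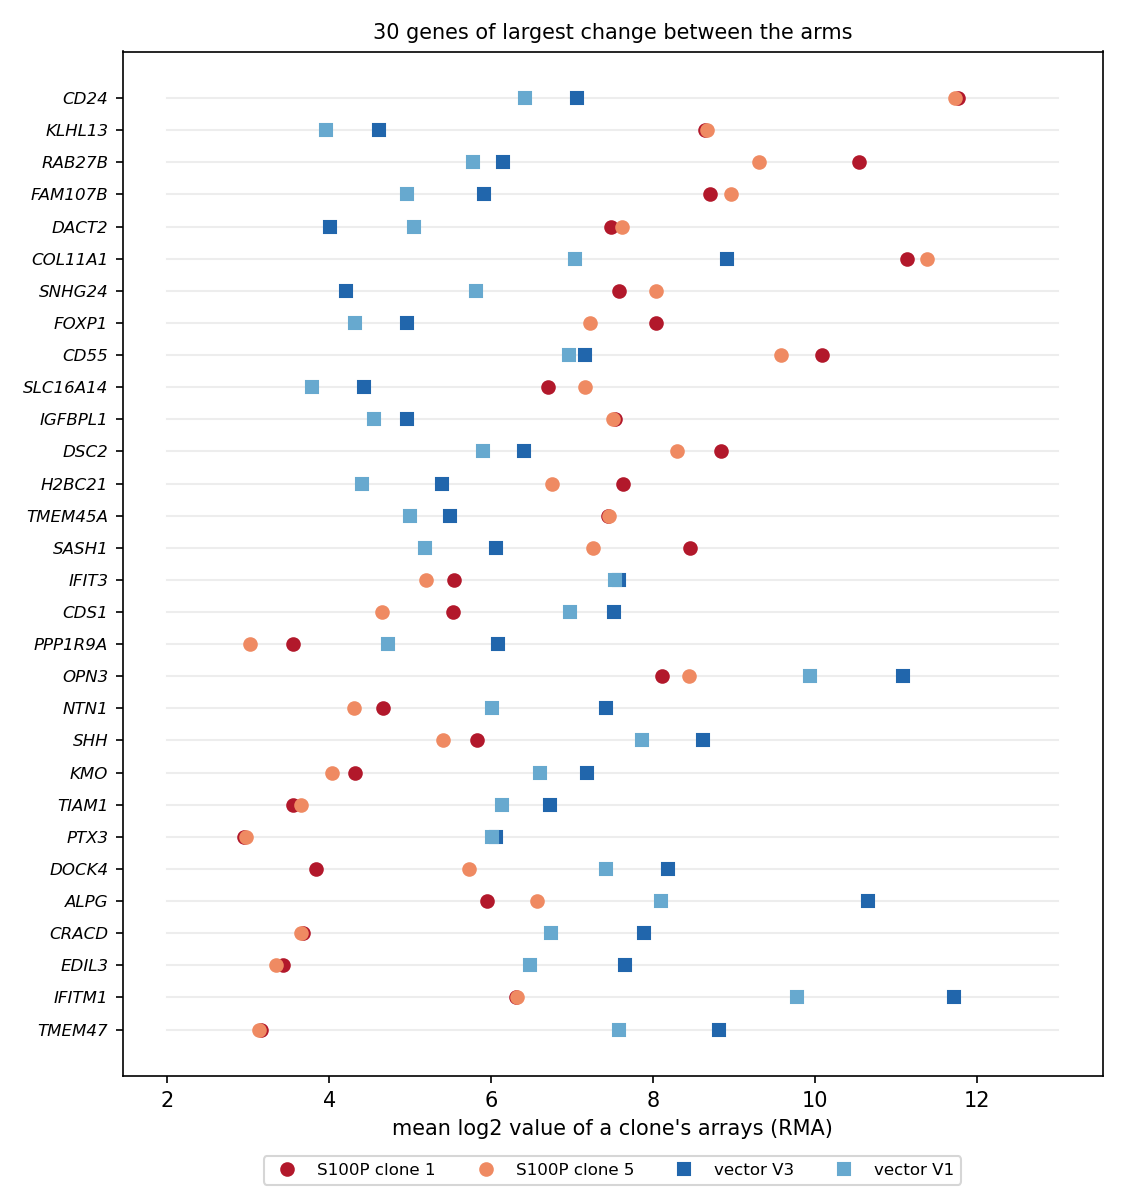
Mean log2 value (RMA) of each clone's arrays for the 30 genes of largest change between the arms, with circles for S100P-labelled clones and squares for vector clones. Both circles lie on one side of both squares for every gene shown, and clones 1 and 5 lie apart for DOCK4, at 3.83 and 5.72.

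Across the array 611 of 54613 probe sets passed the limma test, 424 higher and 187 lower in the S100P-labelled arm. Of these, 302 differed at least 2-fold. By gene, 307 representative probe sets passed, 203 higher and 104 lower. The count was 8 when the arrays of each clone were averaged first, of which 5 probe sets read CD24, and 1 each read PTX3 and LSAMP, the last chosen after its value was seen. The probe set of highest mean for CD24 was not among them, with a log2 difference of 5.00 (adjusted p = 0.0626), nor was KLHL13, with 4.37 (adjusted p = 0.0980), so these calls were lost with the size of change kept. Without V1 the count was 1708, but then only clone V3 stands for the vector arm and spread between vector clones cannot enter. The count was between 159 and 386 without any other single array, and 18 of the 30 genes passed whichever array was left out. The other 12 were DACT2, COL11A1, SNHG24, SLC16A14, H2BC21, SASH1, ALPG, DOCK4, NTN1, OPN3, PPP1R9A and CDS1.

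The type I interferon list fell (adjusted p = 2.07e-04 with cameraPR; 30 members, median log2 difference -0.07, mean -0.36), with an adjusted p = 0.816 with an estimated correlation. IFITM1, IFIT3, IFIT1 and MX2 fell, IFIT1 with a log2 difference of -1.58 (SE 0.29) and MX2 2.09-fold, and no member rose at its representative probe set, adjusted over all probe sets. Adjusted over the list alone, 7 members fell and 3 rose. NF-kB targets fell as a list (adjusted p = 0.00164, median -0.06, 24 members), also with an adjusted p = 0.816 with an estimated correlation. Its lower members were TNFAIP2 (2.92-fold, adjusted p = 0.00406) and the chemokine gene CXCL1 (2.92-fold, adjusted p = 0.0159), and 3 members were lower adjusted over the list alone. TNFAIP2 was not called at its other probe set, 1.40-fold lower. With fry the adjusted p was 0.149 for interferon and 0.385 for NF-kB. Without V1 the interferon list had an adjusted p = 1.74e-07 and the NF-kB list 0.0396 with cameraPR. That fit holds only V3 as vector clone, so these p-values leave out spread between vector clones. Without clone V3 neither passed, with an adjusted p of 0.509 for the interferon list and 0.107 for the NF-kB list, and without clone 5 the NF-kB list had 0.465.

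Cholesterol synthesis rose as a list (adjusted p = 7.02e-04 with cameraPR, median 0.24, 14 members), with an adjusted p = 0.816 with an estimated correlation. Its member MVD, which makes isopentenyl diphosphate, rose 2.01-fold (SE 0.14, adjusted p = 0.0166), and 2 members rose adjusted over the list alone. The list had an adjusted p of 0.149 with fry, 0.0550 without V1 and 0.0755 without clone 1.

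The cell cycle list fell (adjusted p = 6.09e-05 with cameraPR, median -0.44, 35 members) and the list of unfolded protein and amino acid stress genes rose (adjusted p = 6.99e-04, median 0.47, 25 members). With an estimated correlation, 0.545 within the cell cycle list and 0.638 within the stress list, both had an adjusted p = 0.816. The ERK response list rose (adjusted p = 0.0139, median 0.33, 24 members) and the actin regulator list fell (adjusted p = 0.0475, median -0.12, 36 members), both with an adjusted p = 0.816 with an estimated correlation. No member of these 4 lists passed at its representative probe set, adjusted over all probe sets. Adjusted over the list alone, 1 actin member rose and 2 fell, and none of the other 3 lists had a member past the threshold. As values, CDKN1C differed by 1.90 (SE 0.58), EGR1 by 1.96 (SE 0.79), ATF3 by 1.70 (SE 0.82), DDIT4 by 1.37 (SE 0.41) and MYLK by -1.75 (SE 0.36). Without V1 these differences were 0.99 for CDKN1C, 0.87 for EGR1, 1.43 for ATF3, 0.82 for DDIT4 and -1.86 for MYLK. The cyclin-dependent kinase inhibitor CDKN1C was called higher at 3 other probe sets, 2.88-fold to 4.07-fold. These are of a type that can also read near-identical transcripts. A further CDKN1C probe set, 1.03-fold higher, was not called. With fry the adjusted p was 0.385 for each of these 4 lists except actin, with 0.450. Without V1 none passed, with an adjusted p of 0.191 for cell cycle, 0.738 for stress, 0.354 for ERK and 0.354 for actin. Without clone 1 cell cycle (0.512), stress (0.682) and ERK (0.925) did not pass. Without clone V3 neither ERK nor actin (0.107) passed, and without clone 5 actin (0.423) did not. Relative to the mean of the 3 vector arrays, the median of the stress list was 0.63 in clone 1, 0.17 in clone 5, 0.21 in V3 and -0.42 in V1. That of the cell cycle list was -0.62, -0.16, -0.23 and 0.46 in the same order. V3 and V1 make up that mean, so their opposite signs are built in. Of the 2 measures of RNA quality, the ACTB 3' minus 5' difference ran with these lists, highest on the arrays of clone 1 and lowest on V1. The GAPDH difference did not follow that order. It was highest on V3 (0.09 and 0.14), with 0.08 and 0.08 on clone 1, 0.07 and 0.06 on clone 5 and 0.01 on V1.

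**Figure D3:**
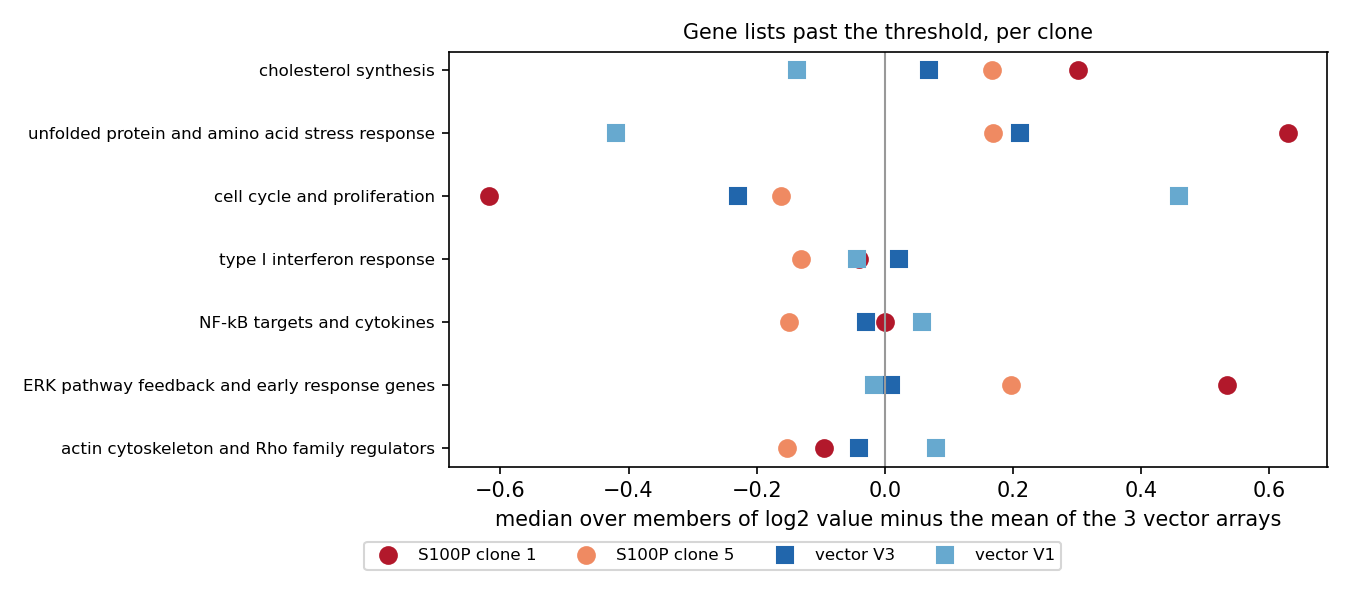
Median over the members of each gene list past the threshold of a clone's log2 value minus the mean of the 3 vector arrays, with circles for S100P-labelled clones and squares for vector clones. For cell cycle, clone 1 lies at -0.62 and V1 at 0.46, while clone 5 (-0.16) and V3 (-0.23) lie side by side. V3 and V1 make up the mean they are set against, so their opposite signs are built in.

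Other lists did not pass, though some members did. The adhesion molecule ALCAM rose 2.44-fold (adjusted p = 0.0193) and the desmosomal gene DSP 1.87-fold (adjusted p = 0.0336). ALCAM was not called at its other probe sets, 1.17-fold and 2.46-fold higher. The cadherin gene CDH11 fell 1.77-fold at its brightest probe set and 12.7-fold at another (limma adjusted p = 0.0159 and 0.00192). At the latter, of a type that can also read near-identical transcripts, the S100P-labelled mean of 2.685 lay below the median of every array. The size of that fold is therefore open. CDH11 was not called at its remaining probe sets, 1.93-fold and 1.045-fold lower. ENO2, a glycolytic enzyme also used as a neuroendocrine marker, rose 1.76-fold (adjusted p = 0.0485). Of 18 other settings ALCAM passed in 10, DSP in 8, ENO2 in 7, and CDH11 in 13 of 17. Of the 9 list members called outside the 30 genes, 7 were lost without clone 5 array b and 7 without V3 array a, and IFIT1 passed in 8 of 18 settings. Adjusted p was 0.992 for adhesion receptors, epithelial markers and mesenchymal markers, 0.341 for hypoxia and glycolysis and 0.868 for endocrine cells. Adjusted over the list alone, 2 adhesion members rose and 2 fell, 2 epithelial members rose and 1 fell, 1 mesenchymal member fell, 2 hypoxia members rose and 3 endocrine members rose.

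In the remaining 12 lists no member passed at its representative probe set, adjusted over all probe sets, and no list did. Adjusted p was 0.782 for the S100 family and 0.577 for S100P partners, of which 2 rose adjusted over the list alone and CDKN1C was called only at the other probe sets given above. It was 0.324 for ductal markers, with 1 member higher and 1 lower adjusted over the list alone, and without V1 the ductal list fell past the threshold (median -0.11, adjusted p = 0.0396). SOX9, a ductal transcription factor, differed by 0.91 (SE 0.17, adjusted p = 0.0549). The adjusted p was 0.992 for proteases, extracellular matrix, TGF-beta targets, Wnt targets and genes used by nearly all cells. In extracellular matrix and in genes used by nearly all cells 1 member each fell adjusted over the list alone. In the last list the transferrin receptor gene TFRC differed by -0.82 (SE 0.16, adjusted p = 0.0546) and was called at 1 other probe set, 2.60-fold lower. Markers of other cell types did not differ between the arms as lists by this test, with an adjusted p of 0.782 for acinar cells, 0.952 for fibroblasts, 0.992 for leukocytes and 0.868 for endothelial cells. THY1, in the fibroblast and mesenchymal lists, was called only at other probe sets, 1.86-fold and 1.82-fold higher. Median, mean and test of a list differed in sign in 9 lists, none of them past the threshold. In RNA quality, the 3' minus 5' log2 difference of ACTB was 0.38 ± 0.13 (SD, n = 4) in the S100P-labelled arm and 0.26 ± 0.08 (SD, n = 3) in the vector arm, exact permutation p = 0.257 (0.514 adjusted over 2 tests). For GAPDH it was 0.07 and 0.08, exact permutation p = 0.771. By clone, ACTB read 0.53 and 0.44 on the arrays of clone 1, 0.29 and 0.27 on clone 5, 0.28 and 0.32 on V3 and 0.18 on V1. GAPDH read 0.08 and 0.08 on clone 1, 0.07 and 0.06 on clone 5, 0.09 and 0.14 on V3 and 0.01 on V1.

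The S100P-labelled clones also differed from each other. In clone 5 the stress transcription factor gene ATF3 was 8.44-fold lower than in clone 1 (log2 difference -3.08, SE 0.15, limma adjusted p = 9.59e-04, 2 against 2 arrays). CREB5 was 6.21-fold lower, RASEF 5.22-fold lower, MAFF 4.59-fold lower and the cadherin gene CDH2 4.37-fold lower. ARFGEF3, SLITRK6 and the chemokine receptor gene CXCR4 were 4.11-fold to 4.29-fold lower. Glutamine synthetase (GLUL) was 5.23-fold higher in clone 5, the receptor gene EPHB6 4.54-fold, the drug efflux pump gene ABCG2 4.51-fold and the heat shock gene HSPA6 4.02-fold. The collagen gene COL5A2, DOCK4, PLAGL1 and SV2A were 2.95-fold to 3.77-fold higher. In all, 1195 probe sets differed, 319 higher and 876 lower in clone 5. None passed with any of the 6 arrays of clones 1, 5 and V3 left out, where limma has 2 residual degrees of freedom, although 4468 to 11537 had an unadjusted p under 0.05.

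The vector clones differed from each other at 3195 probe sets. In V1 the receptor tyrosine kinase gene RET was 13.6-fold lower than in V3 (log2 difference -3.77, SE 0.16, limma adjusted p = 6.78e-04, 1 against 2 arrays). RGS2, a regulator of G-protein signalling, was 12.2-fold lower, and the early response genes FOS and EGR1 were 11.6-fold and 6.87-fold lower. The neuropeptide gene NTS was 9.23-fold lower, GJB6 7.27-fold, the stress gene NUPR1 7.08-fold and CLIC3 6.82-fold lower. BARD1, the partner of BRCA1, was 5.39-fold higher in V1, and ZNF551, PODXL, GAL, SYMPK, MED1, ID3 and SPRY4-IT1 were 3.48-fold to 3.91-fold higher. Of the 3195 probe sets 1405 were higher and 1790 lower in V1. None passed with an array of clone 1 or V3 left out (unadjusted p under 0.05 for 8584 to 11733), and 909 passed without an array of clone 5. V1 is 1 array, and its label has another prefix than those of the other 6, so the clone and any separate handling of that array cannot be told apart.

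Set against the mean of the vector clones, clone 1 differed at 7012 probe sets, 4511 higher and 2501 lower, and clone 5 at 3684, 2383 higher and 1301 lower. These counts use the spread between arrays of one clone, unlike the 611 between the arms. Of those 611, 48 also differed between clones 5 and 1, and 66 between V1 and V3. Independent lists drawn from all 54613 probe sets would share 13.37 and 35.75. Those figures take no account of signal. Among 9907 expressed genes 498 differed between clones 5 and 1 and 1301 between V1 and V3, a larger share than over all probe sets. The overlaps therefore do not show that the calls between the arms were enriched for probe sets that differ within an arm. Among the 30 genes of largest change RAB27B, FOXP1, DSC2, H2BC21, SASH1 and CDS1 were lower in clone 5 than in clone 1, and DOCK4 was higher. With 1 array of the same clone left out the counts fell to 772 and 914 for clone 1 and to 178 and 279 for clone 5. Without an array of another clone they were 4191 to 5106 for clone 1 and 445 to 1345 for clone 5.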

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

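The tests of S100P labels, of the reach of the S100P probe set and of separate handling of V1 were chosen after the results were seen; those on other splits of the arrays and on neighbouring genes were set beforehand. In none of 71 named genes or 3 array measures did 1 of the 4 S100P-labelled arrays stand apart from the others by Dixon's test, which has little reach with 2 arrays of each of 2 clones. The clones labelled S100P overexpressing differed from each other at 1195 probe sets by a direct test, and at 0 with any 1 array of clones 1, 5 or V3 left out (limma; 4468 to 11537 at an unadjusted p under 0.05). The vector clones, which share a label too, differed at 3195, and at 0 in 4 of the 6 fits without 1 array of the other clones, but there V1 cannot be told apart from separate handling of its array. Where a clone was no part of a comparison, the fits without its array a and without its array b gave the same counts. Such fits are not separate checks. Whether S100P had a part in the difference between clones 5 and 1 was not tested. Among the 30 genes of largest change, the log2 difference of clone 5 minus clone 1 was -1.24 for RAB27B, -0.81 for FOXP1, -0.55 for DSC2, -0.89 for H2BC21, -1.19 for SASH1, 1.89 for DOCK4 and -0.875 for CDS1, each past the limma threshold in that contrast.

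The S100P probe set was not detectably higher on the arrays labelled S100P overexpressing, with a log2 difference of 0.27, or 0.99 without clone V3. A candidate explanation is a transgene that lacks the part of the transcript this probe set reads; the probe positions needed for that were not used here. Exchanged labels of the arms stay open too: S100P on V1 minus its lowest S100P-labelled array was -0.71, which speaks against an exchange only if the probe set reads the transgene. A lack of overexpression in these cultures is the biological alternative and was not tested.

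Of the 35 splits of the 7 arrays into 4 and 3, 1, the real one, called as many probe sets as it did. With the clone correlation taken from 2000 probe sets the real split called 627 and the highest of the others 0 by limma. At an unadjusted limma p under 0.05 the others had 975 to 4529, against 6536. Only 3 splits keep the clones whole. The rest set near-identical arrays of a clone against each other, so few calls are built into them. The splits therefore cannot exclude chance differences between clones. Gained or lost chromosome segments as the whole cause are argued against, since the 10 nearest expressed neighbours of called genes moved in the direction of the call by a median log2 shift of 0.0548 (bootstrap interval 0.0273 to 0.0795), against 1.02 for the called genes. Segments as part of the cause stay open, since across 9907 expressed genes the difference between the arms correlated with that of its neighbours at r = 0.202 (0.113 to 0.276; highest of 1000 shuffles 0.0379), though shared regulation of neighbours was not tested. Differences between single clones that have nothing to do with S100P stay open because each arm holds only 2 clones; the 8 calls on clone means do not decide it, as that fit has 2 residual degrees of freedom and the log2 difference of CD24 was 5.00 there (adjusted p = 0.0626) against 4.93.

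Vector clone V1 stood apart from vector clone V3. Across 9907 expressed genes the difference correlated with the median of its 10 nearest neighbours at r = 0.0747 (interval over chromosomes 0.0453 to 0.102; highest of 1000 shuffles 0.0446), above shuffled order but under the level set beforehand for segments, so these may account for a part. Genes are not independent replicates in such a correlation. Separate handling of the V1 array cannot be told apart from the clone, as V1 is the only array with its prefix, and its highest correlation with any other array was 0.990. A difference between the clones themselves stays open and was not tested.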

How the results depend on the processing

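The alternatives were fixed before the data were examined. The 611 probe sets changed between the arms became 1103 without the clone block, 8 on clone means (7 higher), 1906 with array weights, 405 of 18630 without dim probe sets, 302 with a log2 difference of at least 1 and 119 at an adjusted p of 0.01. Fewer probe sets or a stricter threshold explain the last 3; the cause of the others was not tested. The count was 424 by genes, 661 after quantile normalization, 624 with medians centred and 610 with an intensity trend; 69.4% of calls were higher, against 61.4% after quantile normalization and 62.2% with medians centred. Leaving out arrays or clones gave 159 to 1708: 386 and 286 without clone 1 arrays a and b, 314 and 176 without those of clone 5, 159 and 194 without those of V3, 1708 without V1, 678 without clone 1, 1355 without clone 5 and 1675 without V3. Without V1 or a whole clone, an arm holds only 1 clone, so spread between clones of that arm cannot enter. With the array letter as a replicate block, on 6 arrays without V1, 917 passed, against 1708 on the same arrays with the clone block alone. The deviations of equal letters correlated at 0.05, -0.08 and 0.06, so the letters share only a name.

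Of 24 lists 7 passed, 1 with the replicate block, 0 with camera at an estimated correlation (0 at an unadjusted p under 0.05), 0 with fry (2 unadjusted) and 3 to 7 without an array or clone (3 without V1, clone 1 or V3; without V1 these were interferon, NF-kB and the ductal list, which had not passed with all arrays); the cause was not tested. The ERK list turned in test direction without clone 1 (median 0.17, adjusted p = 0.925), with medians of 0.16 to 0.52 over all omissions. Of the 30 genes of largest change, 30 passed without the clone block, after quantile normalization, with medians centred and with the intensity trend, 27 with the letter block, 19 to 29 without 1 array, 24 to 25 without 1 clone and 1 (PTX3) on clone means, where CD24 differed by 5.00 (adjusted p = 0.0626) against 4.93; none turned in direction. Of 39 named calls in all, 21 stayed without clone 5 array b or V3 array a, 19 of them among the 30.

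Between clones 5 and 1 the count of 1195 became 3098 without dim probe sets, 272 at a log2 difference of at least 1, and 0 to 1195 without 1 array. Between V1 and V3 it went from 3195 to 5161, 834 and 0 to 909. For clone 1 against vector 7012 became 1165 at that size and 772 to 5106 without 1 array, and for clone 5 3684 became 590 and 178 to 1345. Fewer residual degrees of freedom, 2 in place of 3, go with the losses. Leaving out V1 keeps 3, since its only array adds nothing to the spread within clones. The 1195 kept there was therefore fixed in advance. No detection calls were used, so how dim signals limit the folds is not known.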

Other observations

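The lists were also tested between single clones, a step chosen after the data were seen. Lists of stress and early response genes were higher in clone 1 than in clone 5 with the preset correlation, and none passed with an estimated one. Unadjusted, camera with an estimated correlation gave p = 0.0319 for stress and p = 0.0426 for ERK response, and p above 0.05 for every other list. The ACTB 3' minus 5' difference, a sign of RNA quality, moved with the stress and early response lists. It was 0.53 and 0.44 on the arrays of clone 1 and 0.29 and 0.27 on those of clone 5. The GAPDH difference hardly moved, at 0.08 and 0.08 on clone 1 and 0.07 and 0.06 on clone 5. The member calls below are lost with any 1 array of clones 1, 5 or V3 left out, as limma then called no probe set between clones 5 and 1 in any of the 6 fits (unadjusted p under 0.05 for 4468 to 11537). Of 25 members of the list of unfolded protein and amino acid stress, 12 were lower in clone 5 and 0 higher, among them ATF3 (-3.08), the transcription factor gene DDIT3 (-1.44) and the pseudokinase gene TRIB3 (-1.17), with an adjusted p = 1.10e-27 by cameraPR and 0.512 with an estimated correlation. Of 24 ERK response genes 9 were lower, among them EGR1 (-1.84), the growth factor gene HBEGF (-1.78) and JUN (-1.58), with an adjusted p = 3.88e-25 (0.512 with an estimated correlation). Of 23 TGF-beta targets 8 were lower, with CCN2 at -1.51 and ID3 at -1.26 (adjusted p = 1.82e-12, or 0.522 with an estimated correlation), and of 24 NF-kB targets 4 were lower (adjusted p = 8.79e-05, or 0.613 with an estimated correlation). Cell cycle genes were higher in clone 5, with 8 members higher and 1 lower of 35, such as CDC25A (0.84) and TOP2A (0.81), adjusted p = 4.56e-11, or 0.522 with an estimated correlation. Epithelial markers rose in clone 5 with an adjusted p = 0.0436 (0.784 with an estimated correlation), which held in 4 of 9 other settings.

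Between the vector clones the same step gave higher cell cycle values and lower stress and epithelial values on the V1 array with the preset correlation, and no list passed with an estimated one. V1 is 1 array, so the variation of that clone was not measured, and each p below holds only if it varies like the other clones. With 1 array of the other clones left out, limma called no probe set in 4 of the 6 fits (unadjusted p under 0.05 for 8584 to 11733). V1 also had the lowest 3' minus 5' differences of the 7 arrays, for ACTB 0.18 against 0.28 and 0.32 on V3, and for GAPDH 0.01 against 0.09 and 0.14. Of 35 cell cycle genes 19 were higher on the V1 array and 1 lower, among them PLK1 (1.19), CCNA2 (1.03) and the proliferation marker MKI67 (1.00), adjusted p = 2.64e-15, or 0.586 with an estimated correlation. Of 25 stress genes 13 were lower and 0 higher, among them the serine synthesis gene PHGDH (-2.47) and asparagine synthetase ASNS (-1.64), adjusted p = 7.52e-20, or 0.586 with an estimated correlation. Of 23 epithelial markers 6 were lower and 2 higher, with an adjusted p = 1.61e-07, or 0.769 with an estimated correlation. The ERK list fell (adjusted p = 1.13e-04; 7 lower and 1 higher) and so did hypoxia and glycolysis (adjusted p = 0.0359), the last in 4 of 8 other settings, both with an adjusted p = 0.794 with an estimated correlation. The median cell cycle value relative to the mean of the vector arrays was -0.62 in clone 1, -0.16 in clone 5, -0.23 in V3 and 0.46 in V1. V3 and V1 make up the mean they are set against, so their opposite signs are built in, here and for stress. The median stress value was 0.63 in clone 1, 0.17 in clone 5, 0.21 in V3 and -0.42 in V1, with the highest ACTB differences in clone 1 and the lowest in V1. The GAPDH difference was highest on V3 instead.

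Expressed genes moved together with their neighbours in gene order (GRCh38) between the arms, at r = 0.202 across 9907 genes (interval over chromosomes 0.113 to 0.276; highest of 1000 shuffles 0.0379) and at r = 0.112 between clones 5 and 1. The genes named next are the run of largest neighbour median in each comparison, chosen after their values were seen, so their counts describe the run and test nothing. Among the 11 genes around PRPS1 10 were higher in the S100P-labelled arm, of which the basement membrane collagen gene COL4A5 (4.14-fold, adjusted p = 0.0101) and the ubiquitin ligase gene RNF128 (2.80-fold, adjusted p = 0.020) passed. PRPS1 itself was level at -0.01. Most genes of this run were also lower in V1 than in V3, such as TSC22D3 (5.78 against 7.13), while RADX and PRPS1 were higher. The differences between the arms thus rest in part on the V1 array. A run around ARMCX5, given below for V1 and V3, was among the largest between the arms too, with a neighbour median of 0.72. Among the 11 genes around EPRS1, 9 were lower in clone 5 than in clone 1, of which 4 passed, and EPRS1 itself was not called. These calls are lost with any 1 array of clones 1, 5 or V3 left out. Between V1 and V3, 8 of 11 genes in a run of related ARMCX, TCEAL and BEX genes were lower in V1 and passed, such as TCEAL8 (-1.63), BEX2 (-1.58) and ARMCX3 (-1.30); limma called no probe set there without an array of clone 1 or V3 (unadjusted p under 0.05 for 8584 to 11733).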
